A study of Mustela putorius furo with 49 samples.

How the data were processed

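The series holds 49 samples from the ferret, a carnivore with a folded cerebral cortex, and 37 of them had values that were analysed. RNA-seq and H3K27ac ChIP-seq were made from microdissected germinal layers of the cortex, the ventricular zone (VZ) and the subventricular zone (SVZ). Tissue came from a gyrus region (A17 or SG in the labels) and a sulcus region (A19 or LS), at embryonic day (E) 30 for the VZ and at E34 for the VZ and the SVZ. H3K27ac is a histone mark found at active promoters and enhancers. The RNA-seq part used 18 libraries in 6 groups of 3, and the ChIP-seq part used 18 H3K27ac libraries in the same 6 groups of 3. A single-cell RNA-seq sample held 2 pools of sorted GFP-positive cortical cells taken at E37, from control embryos and from embryos electroporated at E34 to overexpress Cux2, per the labels. The postnatal day 0 RNA libraries (3 of the gyrus and 3 of the sulcus) were not analysed here, and the 6 ChIP input libraries were not used here.

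The RNA values were signal values: gene counts that the authors had divided by 1 size factor per library, as the low values show, since in each library they are whole multiples of 1 step. The libraries were stranded and read from 1 end, per the labels. FastQC, SAMtools 0.1.19, HTSeq, DESeq2, Bowtie2 and MACS2 are named for the RNA and ChIP samples, without a role or an order, per the submitters' processing notes. Neither the aligner of each assay nor the genome build of the gene counts and peaks is given in the sources used here. The H3K27ac values were CPM (reads in a peak scaled to a common total of reads in peaks) over 51885 peaks merged across samples, as the authors deposited them. Peaks lay on 797 scaffolds and had a median width of 438 bases. Peak positions are printed as deposited, and whether they count from 0 or from 1 is not given in the sources used here. The single-cell file held raw transcript counts (unique molecular identifiers, UMIs) that the authors deposited as a cell by gene matrix, made with the Parse Biosciences combinatorial barcoding kit per the labels. Seurat 4.3.0 is named for it, per the submitters' processing notes, and its gene table names the genome MusPutFur1. Gene symbols came from that gene table, which paired 13300 of the 14343 gene identifiers in the RNA file with a symbol.

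Whole reads could be recovered from every RNA and H3K27ac library: 100% of values lay within 0.1 of a whole read. Recovered reads in genes ranged from 14030239 to 27423077 per RNA library, and reads in peaks from 1683798 to 5519466 per H3K27ac library. The 10 most abundant genes took 3.07% to 3.615% of the reads of an RNA library. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 5.172 to 77.81 for RNA and 3.011 to 8.346 for H3K27ac, so that each library counted as 1 replicate. The labels do not say whether replicates came from separate animals, so every p-value measures the spread between these samples only, which may be technical.

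RNA differences were tested with limma 3.58.1 in R 4.3.3 (linear models with a trend in the prior variance, two-sided) on log2(value + 1), and H3K27ac differences with the same model on log2(CPM + 0.5). One mean per group was fitted over all 18 libraries of an assay, which shared 1 estimate of the spread. Genes with a value of at least 10 in at least 3 libraries were tested, which left 12926, and peaks with at least 1 CPM in at least 3 libraries, which removed none of the 51885. P-values were adjusted by Benjamini-Hochberg over the genes or peaks of a comparison, with a threshold of 0.05. A fold change is on the log2(value + pseudocount) scale, which understates the change of low genes. Comparisons were gyrus against sulcus in each layer and stage, E34 against E30 in the VZ, SVZ against VZ at E34, and the differences of the region effect between stages and between layers. Stage and layer were compared within each region for RNA and over both regions, with 6 libraries a side, for H3K27ac.

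Gene lists numbered 31: markers of cortical cell types and of other cell types a dissection could hold, signalling pathways, cell cycle phases, metabolism and others. Each list was tested against the other genes with camera (preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. Genes named by the rule were, per comparison, up to 10 higher and 10 lower with the largest log2 fold change among called genes that had a symbol, a mean of at least 50 in the higher group and no overlap between the libraries of the groups. To these came up to 4 members of each list with the smallest adjusted p, and in every comparison CUX2, EOMES, PAX6, FLRT1, FLRT3, TNC, PTPRZ1 and ADGRG1, the 8 genes measured here of 12 chosen for their roles in progenitors and folding. Up to 5 higher and 5 lower peaks with a mean of at least 2 CPM and no overlap were named per H3K27ac comparison. Chance alone separates 10% of genes without overlap at 3 libraries against 3.

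In 5 H3K27ac libraries the characteristics name the other region than the title and description do: E30 VZ gyrus library 3, E30 VZ sulcus library 3, E34 VZ gyrus library 6, E34 VZ sulcus library 6 and E34 SVZ sulcus library 5. The title was followed, and counts without these 5 stand beside the H3K27ac counts. Pairing was tested by correlating same-numbered libraries' deviations from group means. Correlations were 0.202, 0.179 and 0.733 between the E30 regions and 0.554, 0.359 and 0.111 between the E34 sulcus layers. Each passed 0.1, so both were also read with the replicate number as a block. Other RNA groups, such as gyrus layers (-0.23, 0.424, 0.299) and E34 VZ regions (0.234, 0.258, -0.103), and H3K27ac failed.

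Cells with at least 500 detected genes were kept, and Scrublet marked 3 of the Control cells and 13 of the Cux2 cells as doublets, a share so low that doublets were largely not removed. The 4126 cells left were log-normalised to 10000 UMIs and clustered in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). Only the highest fixed list with at least 3 markers detected could name a cluster. Its median log2 fold over other cells had to reach 0.3, and the 10 leading genes could not speak for another list. Clusters of shallow cells also needed a list marker among them. The fold minimum was chosen after the data had been seen. Each pool is 1 library, so no test was run. Levels are CPM over the UMIs of a pool or cluster with exact Poisson 95% intervals and shares have exact (Clopper-Pearson) 95% binomial intervals, and both cover counting error only. Bulk gene lists were placed in the clusters by the percentile of their median log2 level among 10000 random lists of equal size matched on mean expression.

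Alternatives were other pseudocounts, filters and scalings (TMM, quantile), array weights, only the compared groups in the fit, the replicate block, a minimum absolute log2 fold change of 1, edgeR 4.0.16 quasi-likelihood tests on recovered reads, DESeq2 1.42.0 on recovered RNA reads, leaving out each library in turn, and other single-cell settings. Up to 100 other splits of the libraries were refitted per comparison. The models were tested on simulated data with 200 changed features. For the E34 SVZ region comparison over 12862 genes, limma recovered 29.58% of 71 genes changed by 1.5-fold, 70.49% of 61 changed by 2-fold and 91.18% of 68 changed by 4-fold, with 8 false calls. For the H3K27ac E34 VZ region comparison over 51883 peaks, it recovered 0% of 69, 19.35% of 62 and 50.72% of 69 at the same folds, with 3 false calls. Promoter H3K27ac was not set against RNA, since no annotation in the build of the peaks was used here.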

Results

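Gene expression (RNA-seq) and the active chromatin mark H3K27ac (ChIP-seq) were measured in the germinal layers of the embryonic ferret cortex, where a gyrus and a neighbouring sulcus will form, and single cells were sequenced after electroporation for Cux2. The series concerns the gene regulation behind cortical folding. Each bulk assay had 3 libraries in each of 6 groups: E30 VZ, E34 VZ and E34 SVZ, each of the gyrus and of the sulcus. The first principal component of the RNA values took 27.9% of the variance. It ran from the E30 VZ libraries (-42.7 to -20.8) over the E34 VZ libraries (0.33 to 15.9) to the E34 SVZ libraries (20.3 to 33.4), with the exception of SVZ gyrus library 3 (2.4), which lay among the VZ libraries. On the second, which took 22.18%, the E30 libraries numbered 3 of both regions (-24.0 and -27.4) stood apart from the other E30 libraries (14.7 to 27.6). Values below are normalised read counts as mean ± SD (n = 3 libraries a group), and log2 fold changes carry their standard error (SE) from limma.

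In the E30 VZ, genes of cholesterol synthesis were lower in the gyrus than in the sulcus as a group, while no single gene passed the test. All 14 measured members of that list had a negative log2 fold change, with a median of -0.30. Examples were NSDHL, a late enzyme of the pathway, at 2287 ± 110 in the gyrus and 2915 ± 203 in the sulcus (log2 fold change -0.35, SE 0.0875, limma adjusted p = 0.846), and FDFT1, which makes squalene, at 4332 ± 461 and 5499 ± 497 (log2 fold change -0.35). The list passed camera (adjusted p = 3.27e-13; adjusted p = 0.00109 with an estimated correlation; fry adjusted p = 0.000811), and 5 members were lower when adjusted over the list alone. TNC, a matrix protein of basal radial glia, stood at 4361 ± 299 and 5767 ± 946 (log2 fold change -0.39, SE 0.145). CUX2, a homeodomain factor of upper-layer neurons and their progenitors, stood at 1551 ± 673 and 1990 ± 141 (-0.45, SE 0.244). FLRT3, a membrane adhesion and guidance protein, stood at 1281 ± 517 and 896.8 ± 131.6 (0.45). These 3 genes and PAX6 (0.06), EOMES (-0.13), PTPRZ1 (-0.11), ADGRG1 (-0.05) and FLRT1 (0.12) had a limma adjusted p of 1.0.

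Other lists passed camera at E30 without a called member, and each was lost with an estimated correlation. Oxidative phosphorylation genes lay lower in the gyrus (camera adjusted p = 0.000783; adjusted p = 0.664 with an estimated correlation). So did the 13 ribosomal protein genes (0.00938; adjusted p = 0.741 with an estimated correlation), whose reads may be shared with processed copies. Guidance and adhesion genes lay higher, 24 of 32 with a positive fold change (0.00214; adjusted p = 0.678 with an estimated correlation). All 7 markers of Cajal-Retzius cells, the reelin-producing neurons of the cortical surface, lay higher too (0.00938; adjusted p = 0.678 with an estimated correlation). Among them were RELN at 6251 against 4119 and EBF3 at 299.9 against 183.1. Markers of the choroid plexus and hem, which border the cortex, were higher in the gyrus (0.0212; adjusted p = 0.58 with an estimated correlation). They came from 1 library. TTR, the main secreted protein of choroid plexus, was at 5588 ± 9660 in the gyrus and 21.6 ± 23.7 in the sulcus, with 16740 in gyrus library 2 and at most 46.9 elsewhere. Adjusted over the list alone, 0 members of these 5 lists passed. Limma called 0 genes in this comparison, while 407 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. With the replicate number as a block limma also called 0.

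By E34 the VZ of gyrus and sulcus differed in 3 genes. LIX1 (ENSMPUG00000004442) was 1990 ± 152 in the gyrus and 717.8 ± 223.4 in the sulcus (log2 fold change 1.51, SE 0.198, limma adjusted p = 0.0108). SEMA3D (ENSMPUG00000018301), a secreted semaphorin that guides axons and migrating cells, was 145.2 ± 25.1 and 43.3 ± 11.6 (1.74, SE 0.269, adjusted p = 0.0419). SCARA3 (ENSMPUG00000000906), a class A scavenger receptor protein, was lower in the gyrus, at 1672 ± 128 against 3233 ± 415 (-0.95, SE 0.151, adjusted p = 0.0424). In all 3 genes the gyrus libraries did not overlap the sulcus libraries. CUX2 (ENSMPUG00000002207) did not pass, at 3129 ± 651 in the gyrus and 7409 ± 652 in the sulcus (-1.26, SE 0.244, adjusted p = 0.0781). It passed with the replicate block (adjusted p = 0.045), by DESeq2, with array weights, with only the compared groups, without each of E30 gyrus libraries 1 and 2, and without E30 gyrus library 2 and E34 VZ gyrus library 3 together (0.000194 to 0.592 over all alternatives). TNC stood at 18110 ± 1645 and 25090 ± 4908 (-0.45, adjusted p = 0.704) and FLRT3 at 860.1 ± 72.7 and 523.3 ± 42.9 (0.72, adjusted p = 0.499). Limma called 2 higher and 1 lower gene, 497 had an unadjusted p under 0.05, edgeR called 9 and DESeq2 44. The count ran from 0 to 29 when single libraries were left out, and all 3 named calls were lost in at least 1 of these fits.

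Cell type lists also separated the E34 VZ regions by camera, none of them with an estimated correlation. Basal radial glia, progenitors that divide away from the ventricle, had lower markers in the gyrus, 10 of 11 negative (camera adjusted p = 3.63e-05; adjusted p = 0.0807 with an estimated correlation) and 4 lower when adjusted over the list alone. Among them were the monooxygenase MOXD1 at 697 against 1677 (log2 fold change -1.26) and PTN, a growth factor that binds PTPRZ1, at 5182 against 8979 (-0.79). Upper-layer genes were lower (0.00186; adjusted p = 0.434 with an estimated correlation). Of these 2 passed when adjusted over the list alone, and POU3F2 was at 436.3 against 939.4. Markers of interneurons, which come from the ventral forebrain, moved the same way, 11 of 12 negative (0.00186; adjusted p = 0.434 with an estimated correlation), for example DLX1 (-0.72) and DLX2 (-0.73). All 7 Cajal-Retzius markers were higher in the gyrus (2.17e-05; adjusted p = 0.378 with an estimated correlation). CALB2 was at 415.8 against 175.9, and 1 member passed when adjusted over the list alone. Deep-layer genes were higher (0.0445; adjusted p = 0.434 with an estimated correlation). FOXP2 was at 315 ± 19.7 against 150 ± 17.2 (1.07, limma adjusted p = 0.14), and 1 member passed over the list alone. Gyrus library 3 held transcripts of other brain territories, with OTX2 at 607.5, DMBX1 at 366 and PAX7 at 140. Without it and E30 gyrus library 2 limma called 3 genes, of which LIX1 was 1, while SEMA3D and SCARA3 lost the call and CUX2 gained one.

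In the E34 SVZ, 15 genes differed between gyrus and sulcus, 8 higher and 7 lower, and CUX2 was among the lower. CUX2 stood at 3052 ± 666 in the gyrus and 9801 ± 1122 in the sulcus (log2 fold change -1.70, SE 0.244, limma adjusted p = 0.0084). LIX1 was again higher, at 2022 ± 103 against 761.2 ± 112 (1.42, SE 0.198, adjusted p = 0.0084), and SCARA3 again lower, at 1192 against 2091 (-0.83, SE 0.151, adjusted p = 0.0407). Also higher in the gyrus were PAPPA2, a protease that frees insulin-like growth factors (562.5 ± 82.1 against 209.8 ± 53.7, 1.44, adjusted p = 0.0084), and TGFB2, a growth factor of the TGF-beta family (1127 ± 107 against 442.9 ± 111, 1.37, adjusted p = 0.0391). So were the matrix protease ADAMTS19 (125.1 ± 21.4 against 28.4 ± 4.78, 2.10, adjusted p = 0.0407) and SLIT3, a guidance ligand (774.2 against 365.4, 1.10, adjusted p = 0.0407). Also higher were LPAR3, a receptor for lysophosphatidic acid (1.26, adjusted p = 0.0084), APCDD1, an inhibitor of Wnt signalling (0.70, adjusted p = 0.0326), and the kinase gene CAMK1G (0.78, adjusted p = 0.0407). Lower in the gyrus were FIBCD1, a receptor for acetylated sugars (-1.81, adjusted p = 0.0469), and HS3ST1, which sulfates heparan sulfate (-1.42, adjusted p = 0.0391). The POU factor POU3F4 (-0.92, adjusted p = 0.0407), the complement component C3 (-0.63, adjusted p = 0.0391) and 1 gene without a symbol were lower too. All 15 genes showed no overlap between the gyrus and sulcus libraries. TNC (-0.35), FLRT3 (0.62), PAX6, EOMES, PTPRZ1, ADGRG1 and FLRT1 did not pass.

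**Figure D1:**
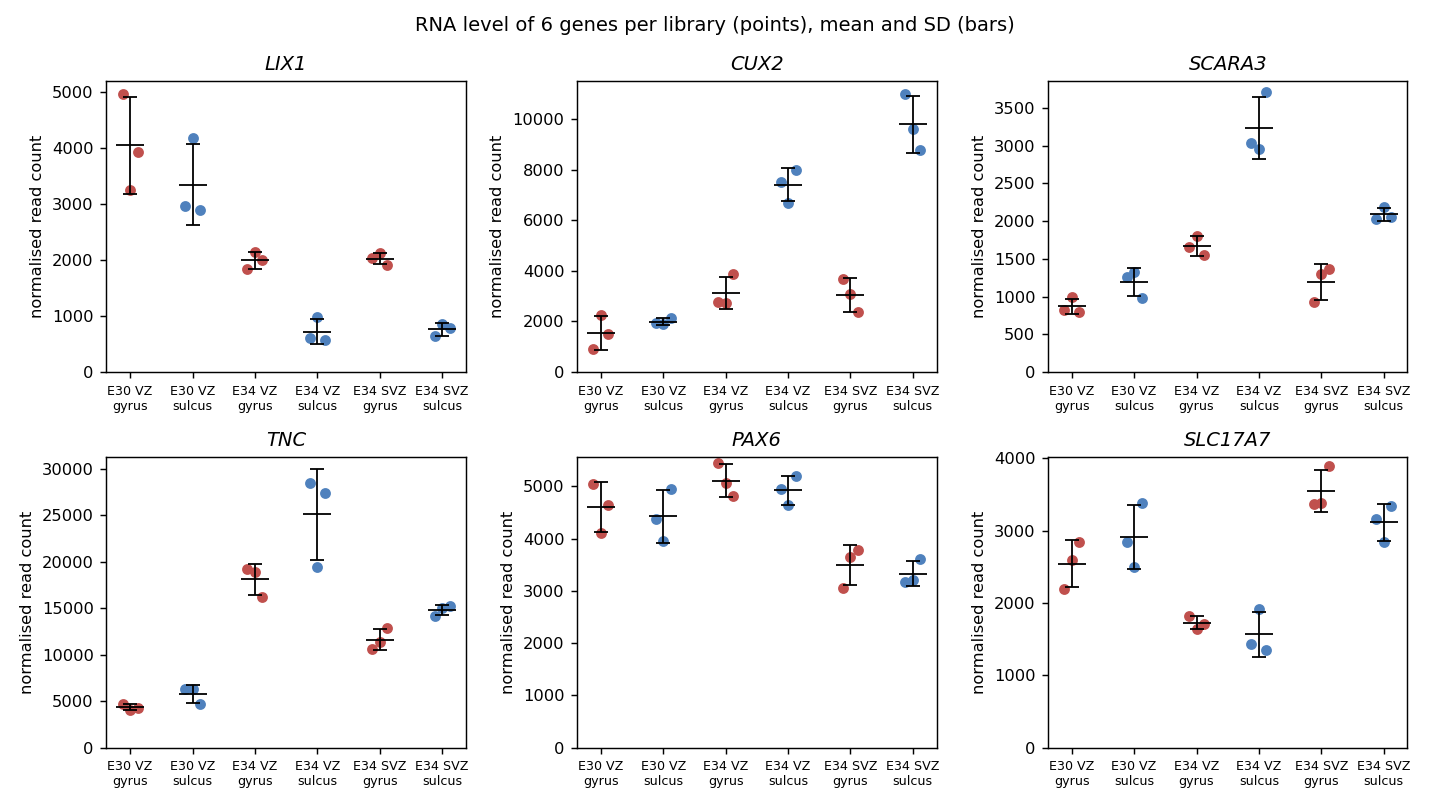
Normalised read count (y axis, starting at 0) of 6 genes in the 6 RNA groups (x axis, red gyrus, blue sulcus); points are the 3 libraries of a group, the horizontal bar is their mean and the whiskers the SD. CUX2 averaged 3052 in the E34 SVZ gyrus and 9801 in the sulcus and LIX1 2022 and 761.2.

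The upper-layer list moved with CUX2 in the SVZ. All 7 measured members had a negative fold change (camera adjusted p = 3.14e-12; adjusted p = 0.0186 with an estimated correlation; fry adjusted p = 0.0314). CUX2 was called, and 4 were lower when adjusted over the list alone. POU3F2 stood at 341 in the gyrus and 908.9 in the sulcus (log2 fold change -1.40). All 11 markers of basal radial glia were negative (2.02e-06; adjusted p = 0.0181 with an estimated correlation). None was called and 2 were lower when adjusted over the list alone. Examples were MOXD1 (409.7 against 1128, -1.48) and PTN (3714 against 6494, -0.82). Markers of other cell types moved in the same direction. All 9 microglial markers were negative (2.39e-06; adjusted p = 0.01 with an estimated correlation), for example the receptor CSF1R (239.3 against 325.5), and 2 were lower when adjusted over the list alone. Negative too were all 6 markers of the oligodendrocyte lineage (2.43e-06; adjusted p = 0.0874 with an estimated correlation). Astrocyte (0.0246; adjusted p = 0.103 with an estimated correlation), interneuron (0.0246; adjusted p = 0.666 with an estimated correlation) and extracellular matrix genes (0.00905; adjusted p = 0.644 with an estimated correlation) lay lower. All 13 ribosomal protein genes lay higher by a median log2 of 0.10 (0.0246; adjusted p = 0.869 with an estimated correlation). SVZ gyrus library 3, which lay among the VZ libraries on the first principal component, was the lowest SVZ library for oligodendrocyte markers (3.382, others 4.852 to 6.011) and upper-layer genes (8.269, others 8.715 to 9.896).

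In this SVZ comparison 525 genes had an unadjusted p under 0.05, edgeR called 12 and DESeq2 84. Without single libraries the count ran from 0 to 46, and 38 genes were called without the E30 gyrus and E34 VZ gyrus libraries that held genes of other territories. Across the 12926 genes, region fold changes in the E34 VZ and SVZ had a Spearman rho of 0.534 (genes are not independent replicates, and the sulcus libraries of the layers pair by number, so the fold changes are not independent). LIX1 and SCARA3 were called in both layers.

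From E30 to E34, 286 genes rose and 154 fell in the gyrus VZ. TNC rose from 4361 ± 299 to 18110 ± 1645 (log2 fold change 2.05, SE 0.145, limma adjusted p = 4.99e-07). SLC1A3, a glutamate transporter of radial glia and astrocytes, rose from 4018 to 17780 (2.34, adjusted p = 0.000167). TLL2, a tolloid-like protease, rose from 59.5 ± 13.2 to 1033 ± 263 (4.08, SE 0.268, adjusted p = 2.3e-07). ACE, the angiotensin-converting enzyme, rose from 143 ± 12.8 to 1305 ± 184 (3.18, SE 0.154, adjusted p = 4.09e-09). Other large increases were in MAL, a myelin proteolipid (6.32 to 117.2, adjusted p = 0.00479), and HEPACAM, a glial adhesion protein (134.9 to 1155, 3.73, adjusted p = 0.000934). BBOX1, an enzyme of carnitine synthesis (3.91, adjusted p = 0.000309), CRYBG1 (3.19), CCN4 (2.68) and the serotonin receptor HTR1A (2.70, adjusted p = 0.0346) rose as well. CUX2 rose from 1551 ± 673 to 3129 ± 651 (1.09, SE 0.244, adjusted p = 0.018). PTPRZ1, a receptor phosphatase of basal radial glia, rose by 0.87 (adjusted p = 0.00381). DMBX1 (3.64, adjusted p = 0.0462) and PAX7 (3.41, adjusted p = 0.0312), homeobox genes of the midbrain, also passed. Their means at E34 were 136.4 ± 199.4 and 54.3 ± 74.8 and rested on library 3.

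Genes that fell in the gyrus VZ included the secreted glycoprotein STC2 (255.7 to 17.7, log2 fold change -3.79, limma adjusted p = 0.00012), CRABP2, which binds retinoic acid (297.9 to 23.7, -3.54, adjusted p = 1.6e-05), and CHAC1, which degrades glutathione (-3.67, adjusted p = 0.00447). The transcriptional cofactor EYA2 fell too (-2.78, adjusted p = 0.00479). COL21A1 (-2.77), SLC22A15 (-2.16), PTPRE (325.4 to 75.9, -2.10, adjusted p = 2.28e-05), SV2B (-2.02) and ADAMTS19 (-2.02) fell as well. PAX6 (0.15, adjusted p = 0.63), EOMES, the factor of intermediate progenitors (0.35, adjusted p = 0.0688), FLRT3 (-0.51), FLRT1 (-0.83) and ADGRG1 did not pass.

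By list, basal radial glia markers rose in the gyrus VZ: 4 of 11 were called and 7 passed when adjusted over the list alone (camera adjusted p = 6.61e-08; adjusted p = 0.0157 with an estimated correlation). Among the called were STAT3 (log2 fold change 0.61) and the integrin ITGB5 (0.74). All 14 cholesterol genes had a positive fold change (2.54e-06; adjusted p = 0.0187 with an estimated correlation). When adjusted over the list alone 5 passed. Growth factor signalling of the FGF and MAPK pathway changed both ways, with 5 of 18 higher and 2 lower, as many when adjusted over the list alone (0.00191; adjusted p = 0.043 with an estimated correlation). ETV5 (1.35, limma adjusted p = 7.14e-05), ETV4 (1.61) and SPRY2 (0.78), targets of the pathway, rose, and the ligand FGF9 fell (-1.46). Matrix genes rose, 6 of 30 called and 8 over the list alone (2.54e-06; adjusted p = 0.139 with an estimated correlation), such as the proteoglycan BCAN (1.36). Ribosomal protein genes lay lower, 1 of 13 called and 10 over the list alone (6.61e-08; adjusted p = 0.292 with an estimated correlation), with RPS20 at -0.67. Markers of other cell types rose beside them. Of these 2 of 6 of the oligodendrocyte lineage were called and 5 over the list alone (2.17e-05; adjusted p = 0.119 with an estimated correlation), including NKX2-2 (2.43). Of 5 astrocyte markers 1 was called, AQP4 (1.86; list 0.0251; adjusted p = 0.119 with an estimated correlation). Endothelial markers passed camera with no call (0.0391; adjusted p = 0.634 with an estimated correlation). Upper-layer genes rose, 2 of 7 called, CUX2 and INHBA, and 4 over the list alone (0.00854; adjusted p = 0.476 with an estimated correlation). Cajal-Retzius markers lay lower with 1 call, CALB2 (-1.34; list 0.0096; adjusted p = 0.605 with an estimated correlation). Oxidative phosphorylation genes also passed camera (0.025; adjusted p = 0.647 with an estimated correlation).

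The sulcus VZ changed in the same direction from E30 to E34. TNC rose from 5767 ± 946 to 25090 ± 4908 (log2 fold change 2.12, limma adjusted p = 4.7e-07). CUX2 rose from 1990 ± 141 to 7409 ± 652 (1.90, SE 0.244, adjusted p = 0.000174). GRIN2A, a subunit of the NMDA receptor, rose from 4.15 to 102.8 (4.46, adjusted p = 0.000361) and ACE from 158.2 to 1452 (3.18, adjusted p = 4.02e-09). HEPACAM rose from 215.6 to 1919 (3.21, adjusted p = 0.0018) and TLL2 by 3.05 on the log2 scale (adjusted p = 6.22e-06). BBOX1 (3.98), CRYBG1 (3.98), the transcription factor TFAP2D (3.81), MAL (3.69), INSYN2B (2.94) and RFTN2 (2.86) rose too. The largest decrease was in DCT, an enzyme of melanin synthesis, from 632 ± 674 to 4.05 ± 4.75 (-6.16, adjusted p = 0.00296). EYA2 (-4.31, adjusted p = 0.000102), STC2 (-3.69), ADAMTS19 (-3.41), CHAC1 (-3.30), CRABP2 (-3.20), SLC22A15 (-2.95), the ubiquitin ligase gene LNX1 (-2.76) and COL21A1 (-2.65) fell. PTPRZ1 rose (0.84, adjusted p = 0.00351), FLRT3 fell (-0.77, adjusted p = 0.0261) and MOXD1 rose (2.16).

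In the sulcus VZ, 6 of 11 basal radial glia markers rose and 9 passed when adjusted over the list alone (camera adjusted p = 1.05e-08; adjusted p = 0.0105 with an estimated correlation). No other list held its call with an estimated correlation. Of 13 ribosomal protein genes 8 fell and 12 passed over the list alone (5.51e-09; adjusted p = 0.265 with an estimated correlation), among them RPS20 (log2 fold change -0.85). Of 30 matrix genes 8 rose and 11 passed over the list alone (1.8e-07; adjusted p = 0.176 with an estimated correlation). Upper-layer genes rose, 4 of 7 called and 4 over the list alone (0.00184; adjusted p = 0.276 with an estimated correlation). Of 8 deep-layer genes 3 fell (0.0143; adjusted p = 0.276 with an estimated correlation), namely FEZF2 (-0.69), FOXP2 (-1.12) and TBR1 (-0.72). The FGF and MAPK list had 4 higher and 2 lower members, and 6 and 4 over the list alone (0.018; adjusted p = 0.176 with an estimated correlation), with SPRY1 (1.45) and SPRY2 (1.01) higher. Markers of other cell types moved beside these. Interneuron markers had 5 higher and 1 lower of 12, and 7 and 1 over the list alone (0.00107; adjusted p = 0.276 with an estimated correlation). DLX1 (1.69) and ERBB4 (2.04) rose and SST fell (-0.84). The oligodendrocyte list had 1 of 6 called, NKX2-2 (2.65), and 6 over the list alone (0.00107; adjusted p = 0.265 with an estimated correlation). The astrocyte list had 1 of 5 called, AQP4 (1.88; list 0.0293; adjusted p = 0.176 with an estimated correlation). Cajal-Retzius markers had 2 lower, CALB2 (-2.40) and NHLH2 (-3.15; list 0.00263; adjusted p = 0.401 with an estimated correlation). Oxidative phosphorylation genes passed camera (0.00421; adjusted p = 0.524 with an estimated correlation). In the Hedgehog pathway, which did not pass as a list, the targets PTCH1 (0.93) and GLI1 (1.27) rose, and in the Wnt pathway LGR5 (-2.32) and LEF1 (-1.12) fell.

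Limma called 440 genes with stage in the gyrus VZ, 286 higher and 154 lower at E34 (1879 with an unadjusted p under 0.05), and 1001 in the sulcus VZ, 537 higher and 464 lower (3027 unadjusted). The median absolute log2 fold change of the called genes was 0.98 and 0.88. Both regions shared 217 higher genes (11.9 for independent lists) and 133 lower genes (5.53), none in opposite directions, with rho = 0.673 across genes, which are not independent replicates. The E30 libraries numbered 3 pair across regions, so the lists are not independent. Leaving out single libraries gave 209 to 565 genes in the gyrus and 430 to 2000 in the sulcus. DESeq2 called 724 in the gyrus.

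Between the layers of the E34 gyrus, 490 genes were higher and 255 lower in the SVZ than in the VZ. SLC17A7, the vesicular glutamate transporter of cortical excitatory neurons, was 3547 ± 296 in the SVZ and 1728 ± 91.3 in the VZ (log2 fold change 1.04, SE 0.142, limma adjusted p = 0.00363). NEUROD6, a neuronal differentiation factor, was 26430 against 11880 (1.15, adjusted p = 0.0223). PAX6, the factor of apical progenitors, was 3495 ± 389 in the SVZ and 5112 ± 319 in the VZ (-0.55, adjusted p = 0.012). CCNA2, a cyclin of S and G2 phase, was 2006 against 3023 (-0.60, adjusted p = 0.00526), and TNC 11630 against 18110 (-0.64, adjusted p = 0.019). Genes with the largest increases toward the SVZ were the somatostatin receptor SSTR1 (440.1 against 91.4, 2.27, adjusted p = 0.00762), the TGF-beta family member MSTN (2.26, adjusted p = 0.0323), GPR139 (2.19), PKHD1L1 (2.16) and the growth factor FGF18 (2.15, adjusted p = 0.0109). NXPH3 (2.15), the potassium channel subunit KCNV1 (2.04), the muscarinic receptor CHRM1 (2.03), COL21A1 (2.02) and ADAMTSL1 (1.98) followed. Lower in the SVZ were the matrix protein VIT (-1.14, adjusted p = 0.0161), the chaperone CRYAB (-1.12), ANGPT1 (-0.98), HNF4G (-0.90), ANGPTL2 (-0.82), the Wnt effector TCF7L2 (-0.79), MKX (-0.79), CDKN3 (-0.79), ITGA2 (-0.78) and DSG2 (-0.78). CUX2 (-0.04, adjusted p = 0.968), EOMES (-0.29, adjusted p = 0.104), ADGRG1, PTPRZ1, FLRT1 and FLRT3 did not pass.

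None of the gyrus layer lists held its call with an estimated correlation. Of 15 genes of G2 and M phase 9 fell in the SVZ and 15 passed when adjusted over the list alone (camera adjusted p = 3.45e-14; adjusted p = 0.0693 with an estimated correlation). Of 17 S phase genes 8 fell and 14 passed over the list alone (2.47e-12; adjusted p = 0.092 with an estimated correlation), such as MCM4 (log2 fold change -0.50). Apical radial glia markers fell, 4 of 12 called and 7 over the list alone (2.77e-07; adjusted p = 0.0693 with an estimated correlation). The called were PAX6, VIM (-0.62), GLI3 (-0.57) and PARD3 (-0.49). Excitatory neuron markers rose, 4 of 11 called and 5 over the list alone (2.14e-05; adjusted p = 0.0693 with an estimated correlation), for instance TUBB3 (0.69). Of 8 deep-layer genes 2 rose, FEZF2 (0.77) and TBR1 (0.79), with 6 over the list alone (0.000694; adjusted p = 0.092 with an estimated correlation). Basal radial glia markers fell in 2 of 11 genes, TNC and ITGB5 (-0.55; list 0.000631; adjusted p = 0.0693 with an estimated correlation). Matrix genes fell in 6 of 30, with 1 higher and 7 lower over the list alone (0.000694; adjusted p = 0.307 with an estimated correlation). Hedgehog genes fell in 1 of 10, with 2 over the list alone (0.000962; adjusted p = 0.283 with an estimated correlation). Ribosomal protein genes passed camera with no call (0.00335; adjusted p = 0.544 with an estimated correlation). Astrocyte markers had 1 call, GJA1 (-0.60; list 0.0227; adjusted p = 0.092 with an estimated correlation). The interneuron genes SST (0.93) and LHX6 (0.59) and the Cajal-Retzius gene CALB2 (1.48) were higher in the SVZ, though their lists did not pass.

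The sulcus layers differed in a similar way. SLC17A7 was 3114 in the SVZ and 1566 in the VZ (log2 fold change 1.01, limma adjusted p = 0.00168). PAX6 was 3331 and 4926 (-0.57, adjusted p = 0.00671), EOMES 8793 and 12010 (-0.45, adjusted p = 0.0117) and TNC 14800 and 25090 (-0.74, adjusted p = 0.00633). CUX2 did not pass (9801 and 7409, 0.40, adjusted p = 0.391). ADGRG1, an adhesion receptor mutated in a human cortical malformation, did not pass (-0.39, adjusted p = 0.0591). It passed with the replicate block (adjusted p = 0.0156, from 5.13e-06 to 1.0 over all alternatives), by DESeq2 and in other alternatives. The largest increases toward the SVZ were in HS3ST5, a heparan sulfate sulfotransferase (242.8 against 37.8, 2.70, adjusted p = 0.0332), HTR1A (2.70), MSTN (2.56), SMOC2 (2.47), and the synaptic adhesion proteins LRFN5 (2.42) and LINGO2 (2.42). NXPH3 (440.5 against 93.5, 2.40, adjusted p = 0.00376), CNTN3 (2.39) and RASGRF1 (2.39) followed. Lower in the SVZ were ENKD1 (-1.12), BTN1A1 (-0.98), the collagens COL27A1 (-0.98) and COL2A1 (-0.90), HNF4G (-0.95), the Hippo effector TEAD3 (-0.93), KIAA1217 (-0.85), GEM (-0.84), AASS (-0.83) and the glucose transporter SLC2A10 (-0.82, adjusted p = 0.00643).

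**Figure D2:**
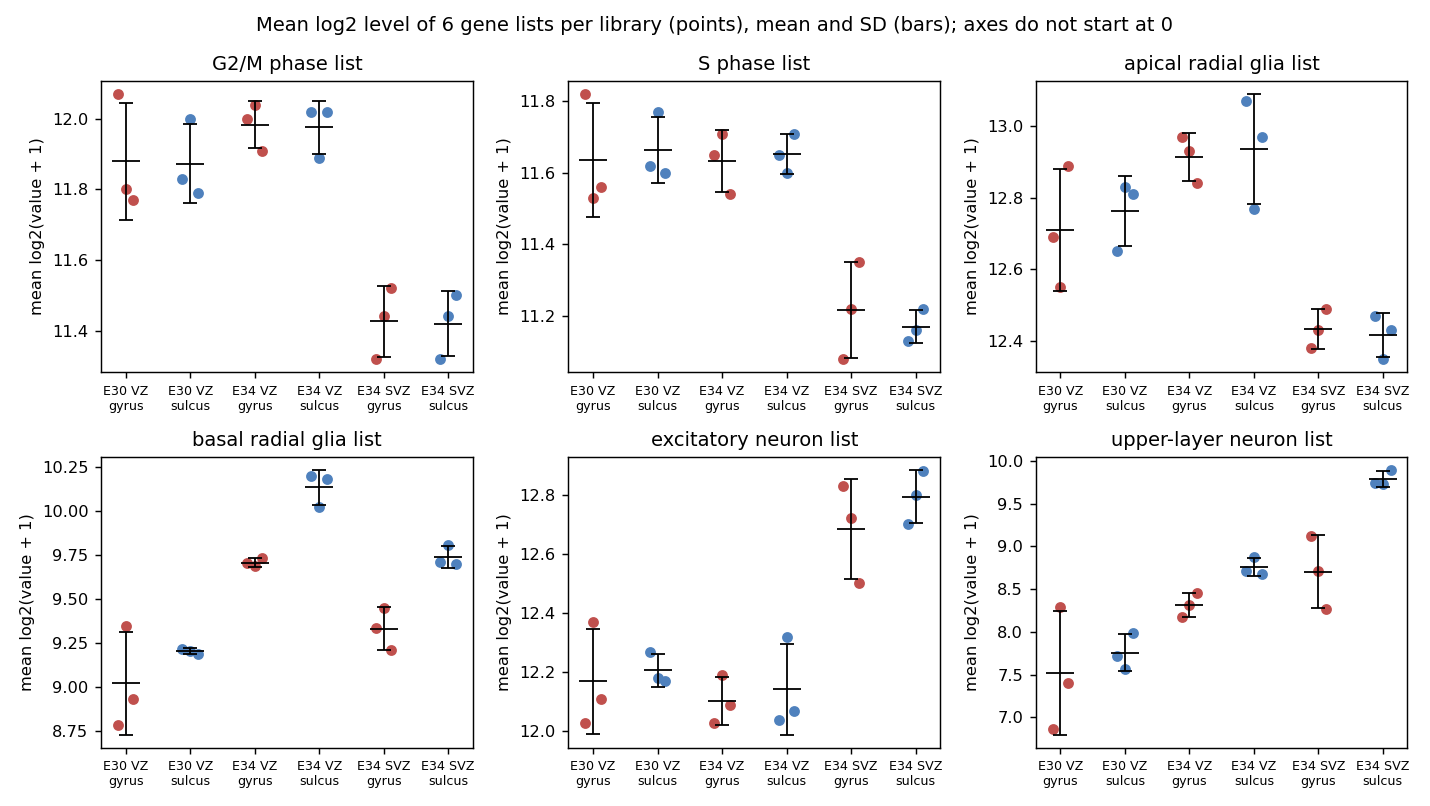
Mean log2(value + 1) of the measured members of 6 gene lists in each library (y axes do not start at 0) for the 6 RNA groups (x axis, red gyrus, blue sulcus); points are the 3 libraries of a group, the horizontal bar is their mean and the whiskers the SD. Cell cycle and apical radial glia lists were lower and excitatory neuron genes higher in the SVZ than in the VZ, and upper-layer genes in the SVZ of the gyrus reached 8.269 in library 3.

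By list, cell cycle genes fell in the SVZ of the sulcus. Of 15 genes of G2 and M phase 11 fell, with 15 passing when adjusted over the list alone (camera adjusted p = 2.9e-12; adjusted p = 0.0467 with an estimated correlation). Of 17 S phase genes 14 fell, with 16 over the list alone (6.24e-13; adjusted p = 0.0705 with an estimated correlation). Apical radial glia markers fell in 5 of 12 genes and 8 over the list alone (4.56e-07; adjusted p = 0.0467 with an estimated correlation). The Notch target HES1 was among them (log2 fold change -0.70). Excitatory neuron markers rose in 5 of 11 and 6 over the list alone (1.12e-05; adjusted p = 0.0467 with an estimated correlation), with NEUROD6 at 1.33. Deep-layer genes rose in 4 of 8 and 7 over the list alone (0.000128; adjusted p = 0.0705 with an estimated correlation). Upper-layer genes rose in 2 of 7, among them MEF2C (1.56), and 4 over the list alone (0.000934; adjusted p = 0.219 with an estimated correlation). Lower were 2 of 11 basal radial glia markers, with 3 over the list alone (0.00161; adjusted p = 0.0705 with an estimated correlation), and 2 of 10 intermediate progenitor markers, EOMES and BTG2 (-0.42; list 0.0375; adjusted p = 0.372 with an estimated correlation). Hedgehog genes fell in 2 of 10 and 6 over the list alone (0.000934; adjusted p = 0.219 with an estimated correlation). So did 3 of 30 matrix genes (0.00255; adjusted p = 0.33 with an estimated correlation) and 2 of 13 Notch genes (0.00379; adjusted p = 0.234 with an estimated correlation). Guidance and adhesion genes had 5 higher and 1 lower of 32, and 7 and 1 over the list alone (0.00763; adjusted p = 0.456 with an estimated correlation). Wnt genes had 1 each way (0.0383; adjusted p = 0.385 with an estimated correlation). Microglial markers were higher in the SVZ, 2 of 9 called and 5 over the list alone (0.00161; adjusted p = 0.0467 with an estimated correlation), with CSF1R at 325.5 against 202.9. Oligodendrocyte markers were higher in 2 of 6, SOX10 (2.26) and PDGFRA (335.7 against 92.0, 1.84), and 4 over the list alone (0.0287; adjusted p = 0.372 with an estimated correlation; adjusted p = 0.0677 with the replicate block).

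Limma called 745 genes with layer in the gyrus, 490 higher and 255 lower in the SVZ (2492 with an unadjusted p under 0.05), and 1109 in the sulcus, 744 higher and 365 lower (2702 unadjusted; 2001 called with the replicate block). The median absolute log2 fold change was 0.68 and 0.72. Both regions shared 418 higher genes (28.2 for independent lists) and 186 lower genes (7.2), none in opposite directions, from separate libraries, with rho = 0.781 across genes, which are not independent replicates. The gyrus count ranged from 77 to 990 and the sulcus count from 205 to 1338 without single libraries. DESeq2 called 1295 genes in the gyrus, and 410 genes were called there without the E30 gyrus and E34 VZ gyrus libraries that held genes of other territories.

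The change of the region difference itself, between E30 and E34 in the VZ or between VZ and SVZ at E34, was called by limma in 0 genes in each case (162 and 70 genes with an unadjusted p under 0.05; edgeR and DESeq2 also called 0). CUX2, which passed the region test in the SVZ and not in the VZ, was thus not shown to differ between layers.

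In the E34 VZ, 256 H3K27ac peaks were higher and 6 lower in the gyrus than in the sulcus (limma, 3735 peaks with an unadjusted p under 0.05, edgeR 316 and 8). Peaks are given by scaffold and position as deposited, and the genes near them were not assigned. The largest increase by the naming rule was at GL897018 487969 to 488226, at 2.93 ± 0.327 CPM in the gyrus and 0.151 ± 0.261 CPM in the sulcus (log2 fold change 2.46, SE 0.582, adjusted p = 0.022). Others were GL898493 3456 to 3669 (13.1 against 2.32 CPM, 2.30, adjusted p = 0.0298), GL897101 1487782 to 1488133 (2.29, adjusted p = 0.0248), GL896970 6660312 to 6660504 (2.20, adjusted p = 0.0128) and GL897499 16364 to 16582 (2.16, adjusted p = 0.00315). Lower in the gyrus were GL896922 6186579 to 6186985 (5.73 against 17.2 CPM, -1.48, adjusted p = 0.0197), GL896922 5693222 to 5693900 (-1.24, adjusted p = 0.0403) and GL897163 962817 to 963429 (-1.21, adjusted p = 0.0087). The others were GL897046 1668978 to 1669879 (-1.21, adjusted p = 0.011) and GL896927 791582 to 792231 (22.8 against 45.3 CPM, -0.97, adjusted p = 0.0245). The 256 higher peaks had a median of 106.3 CPM against 6.757 CPM over all peaks, and a median width of 420 bases against 438. They took 15.53% of the reads in peaks of gyrus library 3, 5.697% and 9.556% in the other gyrus libraries and 2.94% to 3.723% in the sulcus libraries. Without gyrus library 3 limma called 0 peaks (0 to 362 without single libraries). The 256, chosen with it, fell from a median log2 fold change of 1.53 to 1.19, which tests nothing. There were 105 higher and 0 lower without the 5 libraries of conflicting labels.

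**Figure D3:**
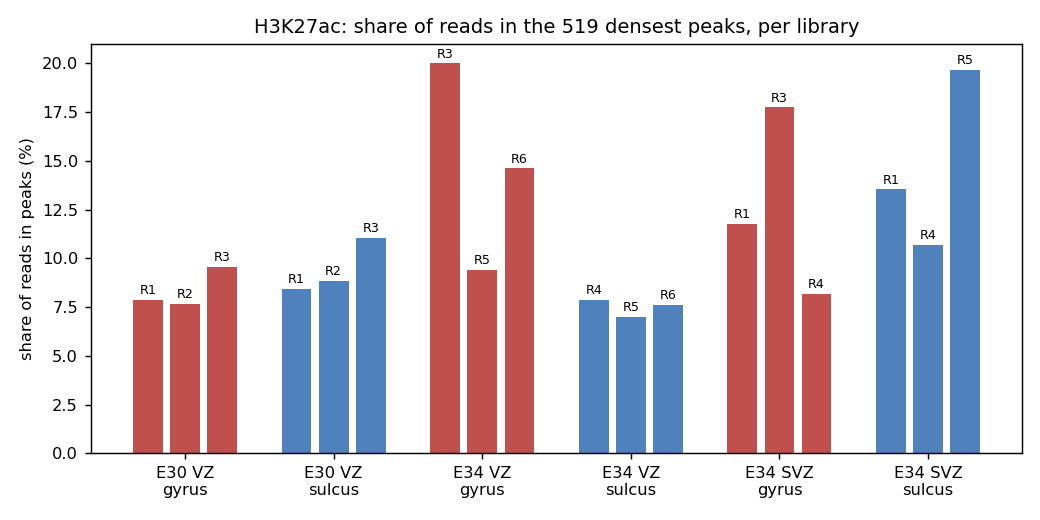
Share of the reads in peaks (y axis, percent, from 0) that fell in the 519 peaks of highest signal per base, for each of the 18 H3K27ac libraries (bars marked with the replicate number, red gyrus, blue sulcus). E34 VZ gyrus libraries ran from 9.396% to 19.99% and E34 VZ sulcus libraries from 6.988% to 7.865%.

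In the E34 SVZ a single peak was higher in the gyrus, GL897013 3992735 to 3995485, at 125 ± 45.7 CPM against 44.1 ± 14.8 CPM (log2 fold change 1.49, SE 0.258, limma adjusted p = 0.0234), and 2922 peaks had an unadjusted p under 0.05. Without the 5 libraries of conflicting labels its log2 fold change was 1.41, with fewer libraries and no call (adjusted p = 0.786, from 1.78e-05 to 0.904 over all alternatives), and edgeR called 0 peaks. In the E30 VZ limma and edgeR called 0 peaks between the regions, also without those 5 libraries, and 1861 had an unadjusted p under 0.05.

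With stage, 198 H3K27ac peaks rose and 429 fell in the VZ from E30 to E34 (limma, 6 libraries a side, 7347 peaks with an unadjusted p under 0.05, edgeR 379 and 294). A strong peak that fell was GL897177 1300415 to 1302554, from 116.7 ± 36.3 to 34.6 ± 21.6 CPM (log2 fold change -1.88, SE 0.22, adjusted p = 4.6e-07), which also fell without the libraries of conflicting labels (-2.59, adjusted p = 2.18e-10, at most 4.36e-05 over all alternatives). GL896905 8433546 to 8433913 (-1.89, adjusted p = 0.00996), GL897361 148188 to 148606 (-1.85, adjusted p = 0.00444), GL896904 8187091 to 8187443 (-1.77, adjusted p = 0.0257) and GL897195 854403 to 854856 (-1.69, adjusted p = 0.0122) fell too. Rising peaks were GL896902 15789376 to 15789644 (3.45 ± 0.915 to 26.0 ± 31.7 CPM, 2.15, adjusted p = 0.00194), GL896918 13813043 to 13813418 (1.77, adjusted p = 0.0399), GL897571 84 to 310 (1.69, adjusted p = 0.00487), GL896929 1777311 to 1777669 (1.60, adjusted p = 0.0245) and GL896954 2685676 to 2685907 (1.53, adjusted p = 0.0335). The balance depended on the scaling, with 31.6% of the called peaks higher as deposited, 55.9% (291 higher, 230 lower) with TMM factors and 45% (229 higher, 280 lower) after quantile normalisation. Without the 5 libraries of conflicting labels 19 rose and 56 fell. Without single libraries the total of 627 ran from 207 (E30 gyrus library 1, 70 higher and 137 lower) to 751.

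Between the layers at E34, limma called 2 higher and 2 lower H3K27ac peaks in the SVZ (5776 with an unadjusted p under 0.05, edgeR 7 higher and 46 lower). The peak without overlap was GL896900 21235185 to 21238408, at 120.9 ± 23.7 CPM in the SVZ and 191.3 ± 21.1 CPM in the VZ (n = 6 libraries a side, log2 fold change -0.68, SE 0.13, adjusted p = 0.0471). The share of higher peaks was 50% as deposited, 9.09% (4 higher, 40 lower) with TMM factors and 62.5% (15 higher, 9 lower) after quantile normalisation, and 6 higher and 5 lower peaks were called without the 5 libraries of conflicting labels. Without single libraries the count of 4 ran from 0, without any 1 of the E30 libraries among others, to 245 without VZ gyrus library 3 and 352 without SVZ gyrus library 4.

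The single-cell sample held 4055 cells of the Control pool and 11761 cells of the pool labelled Cux2, each spread over 6 barcoding wells, with a median of 343 and 378 UMIs per cell. As a check of the pools, CUX2 reached 2324 CPM (95% interval 2282 to 2365, 12183 UMIs) in the Control pool and 1531 CPM (1501 to 1562, 9649 UMIs) in the pool labelled Cux2, which goes against an overexpression of the ferret transcript there. CUX2 was lower in the pool labelled Cux2 in 10 of 10 clusters, with a ratio of 0.352 to 0.786. The sequence of the electroporated construct is not given in the sources used here, and whether its transcript could be counted as CUX2 was not tested. Every direction below is therefore between the pool labelled Cux2 and the Control pool, of 1 library each.

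**Figure D4:**
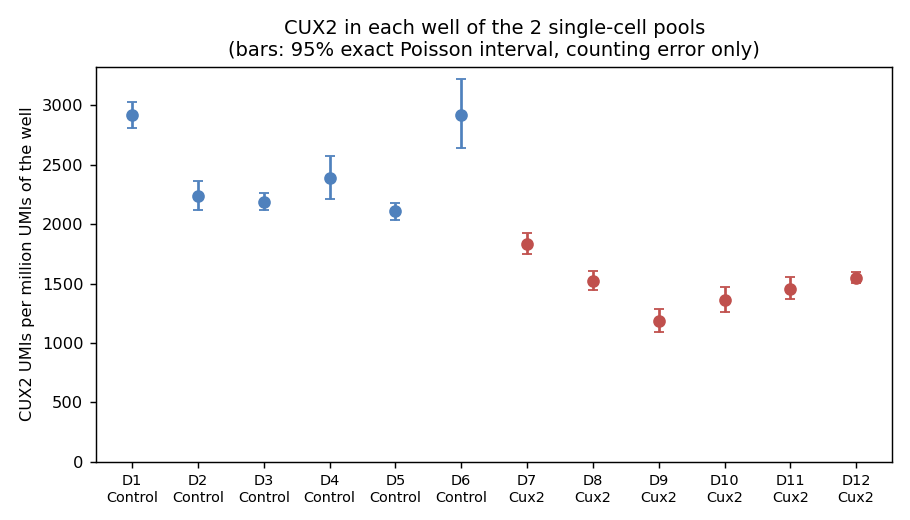
CUX2 CPM over UMIs (y axis, from 0) in each of the 12 wells (x axis, blue Control pool, red pool labelled Cux2); points are the wells and whiskers exact Poisson 95% intervals, which cover counting error only. Control wells lay between 2109 and 2919 and wells of the pool labelled Cux2 between 1188 and 1836.

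Of the cells with at least 500 genes, 1418 were Control and 2724 were from the pool labelled Cux2, with a median of 1512 and 910 UMIs, and they formed 10 clusters. Clusters 1, 2 and 3 were apical-radial-glia-like. Leading genes were GABRB1, SLC1A3 and FOS (cluster 1), IQGAP2 (2), and FOXN4 and the cell division genes AURKB and KIFC1 (3). No marker of the class was among the 10 leading genes of clusters 2 and 3. The median log2 fold was 1.3, 0.41 and 0.32 for its markers and 1.14, 0.37 and 0.25 for basal radial glia markers. These 2 types were not told apart. The class made up 44.0% (41.4 to 46.6) of the Control cells and 38.2% (36.4 to 40.1) of the cells labelled Cux2. Clusters 3 (21.0%) and 2 (17.8%) held most of it in the Control pool, and 1 (19.8%) and 2 (10.5%) in the other. Cluster 4 was excitatory-neuron-like, with no list marker leading, and held 9.82% (8.32 to 11.5) and 11.2% (10.0 to 12.4). The other clusters stayed unnamed and held 46.2% (43.6 to 48.9) and 50.6% (48.7 to 52.5). Cluster 0 (11.2% and 17.8%), led by NEUROD6, had excitatory neuron markers at 0.36. Its highest list, upper-layer genes (0.50), had no leading marker, so neurons may be undercounted. TOP2A and CENPF led clusters 6 and 7, ERBB4 cluster 8 and FLT1 cluster 9. CUX2 was 278.4 against 98.06, 2047 against 1197 and 2118 against 1312 CPM in clusters 1, 2 and 3. In cluster 4 it was 3483 (3182 to 3805) against 2427 (2251 to 2614) CPM. Class shares can be set by the depth gap between the pools. The direction changed in 3 of 5 other settings for apical-radial-glia-like cells. It did in 2 for excitatory-neuron-like cells, and 2 others named none.

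Among the marker genes in the kept cells, BCL11B, a deep-layer factor, was 69.1 CPM (61.68 to 77.17) in the Control pool and 29.3 CPM (23.77 to 35.76) in the pool labelled Cux2 (log2 ratio -1.01 after 10 CPM was added to both, as in all log2 ratios of pools and clusters). EOMES was 186.2 (173.9 to 199.2) and 123.0 (111.3 to 135.6) CPM, ADGRG1 93.2 (84.58 to 102.5) and 53.2 (45.62 to 61.66) CPM, and TBR1 134.9 (124.5 to 146.0) and 87.3 (77.56 to 98.01) CPM. PTPRZ1 (855.8 and 1038 CPM), SLC1A3 (501.3 and 602.9 CPM) and SPARCL1, an astrocyte marker (13.2 and 31.7 CPM), were higher in the pool labelled Cux2. By list, intermediate progenitor markers had a median log2 ratio of -0.47 over 3 genes with enough UMIs (percentile 1.97 of random lists), apical radial glia markers -0.12 (percentile 8.02), basal radial glia markers 0.12 (88.4), excitatory neuron markers -0.15 (7.15), upper-layer genes -0.15 (12.7), deep-layer genes -0.08 (25.8) and astrocyte markers 0.18 (87.5).

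Of bulk genes called between layers in both regions, the 186 higher in the VZ (182 with enough UMIs) were highest in cluster 1. Their median log2 was 1.13 above other cells there (percentile 100) and lowest in cluster 0 (-1.62). The 418 higher in the SVZ (332 with enough UMIs) were highest in clusters 0 (0.33) and 5 (0.26) and lowest in cluster 1 (-0.86). In the pool labelled Cux2 over the Control pool the VZ genes had a median log2 ratio of 0.23 and the SVZ genes -0.22. Cluster 1 held 19.8% and 5.16% of these pools. Percentiles of 100 and 0 are no test of 1 library a pool, and SVZ genes reached 100 in cluster 4 at a median of 0.02.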

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

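The lists of choroid plexus, hem and midbrain genes were tested with predictions written before their values were seen, after TTR, OTX2, DMBX1 and PAX7 had drawn attention to the libraries. All other tests of explanations below, and the counts of splits, were chosen after the result was seen.

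Peaks were called whose H3K27ac region difference changed between stages or layers, which drew attention as a test of the difference. Limma called 119 peaks whose gyrus over sulcus difference in the VZ was more positive at E34 than at E30, and 0 with the opposite sign (2911 peaks with an unadjusted p under 0.05, edgeR 172). Of 100 splits of the libraries 2 gave as many, the real one included, with 235 as the highest other. That share is under 5%, but a split called more, which points to a structure of the samples. The calls rest on single libraries, so chance cannot be excluded. The count was 0 without each of E30 gyrus libraries 1 and 2, E30 sulcus library 3, VZ gyrus libraries 3 and 6 and VZ sulcus library 5, 69 without E30 sulcus library 1, 219 without VZ gyrus library 5, and 54 and 72 without VZ sulcus libraries 4 and 6. Between the layers 129 peaks were called, 8 higher and 121 lower in the SVZ (3103 unadjusted, edgeR 190). Of 100 splits 8 gave as many, with 299 as the highest other, so chance cannot be excluded. This count was 22 and 216 without VZ gyrus libraries 3 and 5, 81 without each of VZ sulcus libraries 5 and 6, 214 and 0 without SVZ gyrus libraries 3 and 4, and 59, 265 and 0 without SVZ sulcus libraries 1, 4 and 5. Both counts were 0 without the 5 libraries of conflicting labels, and 95% and 92.2% of these peaks were among the densest 1% of all peaks.

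Gene lists also differed in their region difference by camera, with 0 members called by limma and none of them passing fry. Between the stages, the gyrus over sulcus difference of cholesterol synthesis genes was more positive at E34 (adjusted p = 7.65e-07; adjusted p = 0.019 with an estimated correlation), for 13 of 14 genes, by a median log2 of 0.28. Their median was -0.30 at E30 and -0.0023 at E34. Interneuron markers moved the other way (0.00855; adjusted p = 0.735 with an estimated correlation). That of ribosomal protein genes was more positive at E34 (0.0365; adjusted p = 0.773 with an estimated correlation), with a median of -0.14 at E30 and 0.02 at E34. Between the layers, microglial markers had a lower gyrus over sulcus difference in the SVZ than in the VZ (2.22e-05; adjusted p = 0.0178 with an estimated correlation). The same direction was seen for markers of the oligodendrocyte lineage (7e-06; adjusted p = 0.109 with an estimated correlation) and for upper-layer genes (0.000117; adjusted p = 0.284 with an estimated correlation). Cajal-Retzius (0.000354; adjusted p = 0.399 with an estimated correlation) and astrocyte markers (0.00962; adjusted p = 0.109 with an estimated correlation) moved this way too. Oxidative phosphorylation (0.0355; adjusted p = 0.808 with an estimated correlation) and glycolysis genes (0.0436; adjusted p = 0.808 with an estimated correlation) moved up, and both lost the call with TMM factors (adjusted p = 0.0536).

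Markers of other brain territories stood out in 2 RNA libraries. In E30 VZ gyrus library 2, 10 of 15 genes of a second choroid plexus list (66.7%) had their highest value of the 18 libraries, against 5.79% of all tested genes, with HTR2C at 692, TRPM3 at 416.1 and SLC4A5 at 277, while SLC4A10 (1252) and SLC29A4 (797.7) were not highest. TTR, OTX2 and the other genes of the first list were not in this one. This is consistent with choroid plexus epithelium in that sample. Of 9 hem genes 3 (33.3%), among them LMX1A of the first list, were highest there, which leaves hem tissue open. In E34 VZ gyrus library 3, 6 of 13 midbrain genes (46.2%, against 1.81% of all tested genes) were highest, with GATA3 at 83.1 and BARHL1 at 35.7 (DMBX1, PAX7 and OTX2 were not in the list), so that midbrain tissue may be present but is not settled by this list; a biological difference was not tested.

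The higher H3K27ac peaks of the E34 VZ gyrus can be set against 3 explanations. With the region taken from the characteristics 0 peaks were called, but the peaks were found with the other labels and the count fell to 0 without library 3 alone, so the right labels cannot be told apart by it. Of the 262 called peaks 205 (78.2%) were among the densest 1% of all peaks, a class whose share of reads also ran from 10.69% to 19.66% within the SVZ sulcus group, so a signal that varies between libraries is a candidate explanation. Whether library 3 alone is the source stays open, since the median log2 difference of the densest peaks was 0.752 with it and 0.538 without it. A difference between gyrus and sulcus tissue also stays open.

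CUX2 was lower in the pool labelled Cux2, against the direction that overexpression of the counted transcript would give. The makeup of clusters is argued against by a median ratio of 0.641 within clusters, and depth per cell by ratios of at most 0.775 in 4 ranges of genes per cell. An exchange of the pool names cannot be told apart from the names as given, because after thinning to 1000 UMIs 1 cell in each pool had 10 or more CUX2 UMIs (0.1027%, 0.0026 to 0.571, in the Control pool and 0.08636%, 0.00219 to 0.48, in the other). A construct whose transcript is not counted as CUX2 may also leave the ferret gene lower, which was not tested, and no biological explanation was tested.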

How the results depend on the processing

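The pseudocounts, filters, scalings, models, and the leaving out of single libraries and of the 5 libraries with conflicting labels were chosen before the data were examined. The fits without 2 RNA libraries, with the share of reads in the densest peaks as a covariate, and without 5 libraries and E34 VZ gyrus library 3 were chosen after seeing the data. Except where a cause is named, the cause was not tested. Of the named genes and peaks with a call, 8109 values under an alternative kept their direction and side of the threshold, 1366 lost the call and 0 reversed. Of those without a call, 1726 kept direction and side, 41 gained a call and 53 reversed. Calls were kept in every alternative by 21 of 54 named genes with stage in the gyrus, 39 of 80 in the sulcus, 3 of 61 with layer in the gyrus and 5 of 76 in the sulcus. None of the 3 and 14 named genes of the E34 VZ and SVZ region comparisons did. For H3K27ac it was 4 of 10 named peaks with stage, and 0 of 10, 0 of 1 and 0 of 1 for the E34 VZ region, the E34 SVZ region and layer.

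RNA counts moved as follows. In the E34 VZ region comparison (3) limma called 7 with a pseudocount of 5, 50 with only the compared groups and 27 with the replicate block, edgeR called 9 and DESeq2 44. In the SVZ region comparison (15) it was 57 with the block, 84 by DESeq2, 9 at an absolute log2 fold change of at least 1 and 38 without the 2 libraries. For stage in the gyrus (440) it was 172 with only the compared groups, 724 by DESeq2 and 212 at the larger fold change. For stage in the sulcus (1001) it was 362 with only the compared groups and 423 at the larger fold change. For layer in the gyrus (745) it was 1781 with only the compared groups, 1662 with the block, 1295 by DESeq2, 175 at the larger fold change and 410 without the 2 libraries. For layer in the sulcus (1109) it was 2001 with the block, where the replicate numbers pair, and 350 at the larger fold change. The E34 regions and gyrus layers failed the pairing rule, and, as at E30, not every library matched its own number best. In the E30 region comparison (0) DESeq2 called 1. With array weights the counts were 864, 5094, 1787, 2998, 7120 and 6893 in this order from the E34 VZ region to layer in the sulcus, and 339 for the region difference between layers. Their iteration stopped before converging, with weights from 0.15 (E30 VZ gyrus library 3) to 32.2 (E34 SVZ sulcus library 2), so these counts rest on few libraries.

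The number of lists past camera fell with an estimated correlation to 1 of 6 (E30 region), 0 of 5 (E34 VZ region), 3 of 8 (SVZ region), 3 of 11 and 1 of 11 (stage in gyrus and sulcus), 0 of 10 and 4 of 15 (layer in gyrus and sulcus), and 1 of 3 and 1 of 7 (region difference between stages and layers). By fry it was 1 (E30 region), 0 (E34 VZ region), 3 (SVZ region), 7 (stage in the gyrus), 0 and 0 (region differences). Without single libraries it ran from 1 to 11, 3 to 7, 5 to 11, 8 to 13, 9 to 12, 9 to 13, 13 to 17, 1 to 10 and 4 to 10 in the first order.

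H3K27ac counts moved as follows. In the E34 VZ region comparison (262) limma called 170 with the block, 105 without the libraries of conflicting labels, 0 with regions from the characteristics, 0 with the covariate and 0 without 5 libraries and E34 VZ gyrus library 3. The covariate is made largely of the same peaks and overlaps with the groups, so it tests nothing. It took the median log2 fold change of these peaks from 1.53 (SE 0.299) to 0.233 (SE 0.233). In the SVZ region comparison (1) it was 0 with a pseudocount of 0.1, 0 with TMM factors, 60 with the block, 0 by edgeR, 0 without the conflicting libraries, 0 by characteristics and 0 without 6 libraries. For stage (627) it was 962 with array weights, 75 without the conflicting libraries, 396 by characteristics and 125 without 6 libraries. For layer (4) it was 0 with a pseudocount of 0.1, 21 with 2, 0 with the CPM 5 filter, 44 with TMM, 24 with quantile normalisation, 0 with only the compared groups, 210 with the block, 140 with array weights and 53 by edgeR. It was 11 without the conflicting libraries, 0 by characteristics, 0 with the covariate and 405 without 6 libraries. The region difference between stages (119) gave 0 with a pseudocount of 0.1, 71 with the CPM 5 filter, 197 with only the compared groups, and 0 without the conflicting libraries, by characteristics, with the covariate and without 6 libraries. That between layers (129) gave 31 with a pseudocount of 0.1, 73 with quantile normalisation, 24 with only the compared groups and 205 with the block. It gave 0 without the conflicting libraries, by characteristics, with the covariate and without 6 libraries.

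Without single RNA libraries the counts ran from 0 to 0 (E30 region and both region differences), 0 to 29 (E34 VZ region), 0 to 46 (SVZ region), 209 to 565 and 430 to 2000 (stage in gyrus and sulcus), and 77 to 990 and 205 to 1338 (layer in gyrus and sulcus). A library outside a comparison acts on it through the shared spread. The E34 VZ region count was 23, 29 and 6 without E30 gyrus libraries 1, 2 and 3, 0 without each of E34 VZ gyrus libraries 1, 2 and 3, 0, 18 and 0 without VZ sulcus libraries 1, 2 and 3, and 1 without each of SVZ gyrus library 2 and SVZ sulcus libraries 2 and 3. The SVZ region count was 36 and 46 without E30 gyrus libraries 1 and 2, 6 without each of E30 sulcus libraries 1 and 2, 4 without each of VZ gyrus libraries 1, 2 and 3, and 5 without VZ sulcus library 1. It was 2, 0 and 0 without SVZ gyrus libraries 1, 2 and 3, and 0, 5 and 4 without SVZ sulcus libraries 1, 2 and 3. The gyrus stage count was 266 without E30 gyrus library 1 and 209, 236 and 274 without E34 VZ gyrus libraries 1, 2 and 3. The sulcus stage count was 486 and 2000 without E30 sulcus libraries 2 and 3, and 430 and 437 without VZ sulcus libraries 1 and 3. The gyrus layer count was 77, 204 and 336 without VZ gyrus libraries 1, 2 and 3, and 84 and 155 without SVZ gyrus libraries 1 and 2. The sulcus layer count was 252 and 205 without VZ sulcus libraries 1 and 3, and 482 and 518 without SVZ sulcus libraries 2 and 3.

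Without single H3K27ac libraries the counts ran from 0 to 0 (E30 region), 0 to 362 (E34 VZ region), 0 to 2 (SVZ region), 207 to 751 (stage), 0 to 352 (layer), and 0 to 219 and 0 to 265 (region difference between stages and layers). The E34 VZ region count was 0 without gyrus library 3. The SVZ region count was 0 without each of gyrus libraries 1 and 4 and sulcus libraries 1 and 5, and 2 without sulcus library 4. The stage count was 207, 417 and 295 without E30 gyrus libraries 1, 2 and 3, 352, 324 and 256 without E30 sulcus libraries 1, 2 and 3, 336 without VZ gyrus library 3, and 269 and 276 without VZ sulcus libraries 4 and 6. The layer count was 0 without each E30 library, 245, 0 and 10 without VZ gyrus libraries 3, 5 and 6, and 0, 0 and 23 without VZ sulcus libraries 4, 5 and 6. It was 0, 0 and 352 without SVZ gyrus libraries 1, 3 and 4, and 0, 95 and 23 without SVZ sulcus libraries 1, 4 and 5.

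The log2 fold changes that changed sign had no call, and lay between -0.07 and 0.12 with all libraries. PAX6 in the region difference between stages was 0.0089 with TMM and 0.0081 by edgeR, and in that between layers -0.0013 with TMM, -0.0025 with quantile normalisation and -0.0297 without the 2 libraries. CUX2 between the gyrus layers was 0.0713 with array weights and 0.1251 without the 2 libraries. FLRT1 in the region difference between layers was 0.0956 with array weights. ADGRG1 without the 2 libraries was 0.078 in the E30 region and -0.0808 in the region difference between stages. Without single libraries, E30 region values ran from -0.0218 to 0.1411 (PAX6), -0.2037 to 0.078 (ADGRG1) and -0.2754 to 0.5076 (FLRT1). In the region difference between stages they ran from -0.0881 to 0.0748 (PAX6), -0.1034 to 0.1783 (ADGRG1), -0.0356 to 0.1437 (PTPRZ1) and -0.2361 to 0.0815 (TNC). In that between layers they ran from -0.2555 to 0.068 (PTPRZ1), -0.0465 to 0.1073 (PAX6) and -0.2045 to 0.1575 (FLRT1). CUX2 between the gyrus layers ran from -0.1897 to 0.1318, ADGRG1 in the E34 VZ region from -0.1105 to 0.0229 and EOMES in the SVZ region from -0.0152 to 0.1794.

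Single-cell class shares moved with every setting, in Control and in the pool labelled Cux2 in this order. Apical-radial-glia-like cells (44.0% and 38.2%) were 6.15% and 21.4% at resolution 0.5, 23.5% and 29.6% at 1.5, 39.8% and 29.7% with at least 300 genes, 23.4% and 17.4% with at least 1000 genes, and 6.49% and 23.4% with doublets kept. The direction between the pools thus changed in 3 of these 5 settings. Excitatory-neuron-like cells (9.82% and 11.2%) were 0% and 0% at resolution 0.5, 14.8% and 13.4% at 1.5, 15.5% and 14.8% with at least 300 genes, 0% and 0% with at least 1000 genes, and 9.52% and 10.2% with doublets kept. Unnamed cells (46.2% and 50.6%) were 93.9% and 78.6%, 61.7% and 57.0%, 30.5% and 29.1%, and 76.6% and 82.6% in these settings, and 71.8% and 47.4% with doublets kept. CUX2 was lower in the pool labelled Cux2 in every cluster with cells of both pools in each setting, with median ratios of 0.591, 0.714, 0.641, 0.727 and 0.688. Depth limits these shares, since most cells held fewer than 500 genes.

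The comparison of H3K27ac at promoters with RNA, and its alternative of the nearest gene within 50 kb, were not run, since no annotation in the build of the peaks was used here.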

Other observations

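The counts of splits below were chosen after the results were seen. For the RNA comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 5%. The real split was the only 1 of 10 to give as many calls in the E34 VZ region (3, highest other 0), the E34 SVZ region (15, highest other 0), stage in the gyrus (440, highest other 0) and in the sulcus (1001, highest other 0), and layer in the gyrus (745, highest other 0) and in the sulcus (1109, highest other 0). In the E30 VZ region the real split called 0 genes (407 unadjusted, edgeR 0, DESeq2 1, 0 with the replicate block), so that 10 of 10 splits gave as many by construction. With pairs taken by number, the 3 other splits that parted all 3 pairs, as the real one does, also called 0. Of the 6 that parted 1 pair, those that called 1510, 772 and 422 genes kept the libraries numbered 3 together, 1 that did so called 0, and the 2 that parted them called 0 and 1. This points to a structure of the E30 samples in which the libraries numbered 3 stand apart. In the sulcus layers, which pair, both kinds of split called 0. The region differences between stages (162 unadjusted, edgeR 0, DESeq2 0) and between layers (70 unadjusted, edgeR 0, DESeq2 0) also had 0 calls, so 100 of 100 splits gave as many by construction, with up to 1419 and 0, which says nothing about chance.

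For H3K27ac the region comparisons again have 10 splits, too few for such a share. In the E30 VZ 10 of 10 gave at least the 0 calls of the real one (1861 unadjusted, edgeR 0) by construction, with 2 as the highest other. In the E34 VZ 1 of 10 gave 262, with 0 as the highest other, and in the E34 SVZ 3 of 10 gave 1 or more, with 207 as the highest other, which points to a structure of these samples. For stage only the real split of 100 gave 627 peaks (highest other 93), the lowest possible share. For layer 13 of 100 gave 4 or more, with 361 as the highest other, so chance cannot be excluded, and the higher count points to a structure of the samples.

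A list of motile cilia genes, run without a prediction, had 9 of 12 members (75%) at their highest in E30 VZ gyrus library 2, with FOXJ1 at 129.9.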
